A study of Mus musculus with 6 samples.

How the data were processed

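The series holds bulk RNA-seq of MC3T3-E1 cells (subclone 4), an osteoblast-like line established from mouse calvaria, the flat bone of the skull. Cells received vehicle or PTH(1-34), the amino-terminal fragment of parathyroid hormone that activates the PTH receptor. There were 3 libraries per group, numbered 1 to 3 in both groups, and the group and number of each library were taken from its title. The labels give 2 treatment times: the sample characteristics state 30 min and the treatment protocol states 2 h, so the time behind every value below is uncertain. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

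Per the labels' protocols, RNA was isolated with TRIzol, libraries were made with a stranded mRNA kit, and paired-end reads were assembled into transcripts whose abundance the authors estimated as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) with Cufflinks. The submitters' processing notes name the mouse build mm10. The aligner, the tool versions and the annotation release are not given in the sources used here. The deposited table lists 1 FPKM value per transcript and library for 37478 Ensembl transcripts under 13659 gene symbols and 13694 gene identifiers, and all of these transcripts have the status OK. One further line held no values. The authors' comparison of the groups is deposited in the same table as a log2 fold change, a p-value and a q-value per transcript, per the file headers. Its groups are named only q1 and q2, and 3 further columns of that comparison were not used.

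Transcript FPKM values were summed per gene symbol, so a gene-level value covers only the transcripts present in the table. There were 35 symbols with more than 1 gene identifier, and 19 symbols had been turned into dates by a spreadsheet, of which 1 held more than 1 identifier. Date-like symbols stayed in the counts and are not named. Of the 13694 gene identifiers, 13470 were found in GENCODE M21, the annotation of GRCm38 (the same assembly as mm10), as were 97.5% of the transcripts. For 99.97% of the transcripts whose gene was found, the deposited locus overlapped the annotated gene. Gene coordinates are those of GENCODE M21, 1-based.

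FPKM values are not counts. The low values showed no whole-read steps, so the depth of the libraries is unknown, and no counting interval or detection floor is given. The FPKM totals ranged from 618221 in PTH 2 to 853916 in vehicle 3. The short RNA gene Mir5105 alone took between 19.0% (vehicle 2) and 39.6% (PTH 1) of these totals. Without 3 short RNA genes, Mir5105 among them, the totals ranged from 434475 (vehicle 3) to 445242 (PTH 1). Dividing by the total (TPM) therefore passes the variation of a few short RNA genes on to every gene.

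The test was limma 3.58.1 (R 4.3.3; lmFit, and eBayes with an intensity trend) on log2(FPKM + 0.5), for the 11628 genes with a mean FPKM of at least 1 over the 6 libraries, without a block, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. The same test was run on 21983 transcripts. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, over the 18 of 24 lists with at least 5 tested genes. fry asks whether a list's genes move, on balance, one way and does not compare them with other genes. Unequal change between the transcripts of a gene was tested with limma's diffSplice (Simes p per gene, Benjamini-Hochberg). Tables were joined and plotted with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The design, the gene lists, the rule for named genes and the settings to vary, except those said to be chosen later, were fixed before the data were examined.

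On simulated data with 200 of 11628 genes changed, the gene test recovered 54% of the genes changed by 0.5 on the log2 scale, 88% of those changed by 1 and 98% of those changed by 2 or by 3, with 6 false calls among 175. With nothing changed it made 0 calls. For the transcript test, run on 21983 simulated transcripts, the shares were 36%, 82%, 88% and 96%, with 3 false calls among 154. Noise was drawn independently per gene or transcript, changes had random signs, and no library-wide shift, trend with level or shared number was simulated. These figures therefore do not cover errors that come from the scaling or from paired libraries.

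The named genes are Nfil3 and Naca, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose libraries did not overlap between groups, and for each list up to 4 members with the largest change past the threshold, or, where none passed, up to 2 with the highest mean FPKM. Symbols starting with Gm or ending in Rik, and Mir and Snor genes, were counted and not named. A few genes and transcripts outside this rule are named where the text says so, and some list members that the rule selects are not reported here.

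Whether the shared numbers pair the libraries was checked from the deviations of each library from its group mean across genes. The correlation between the vehicle and PTH libraries of the same number was 0.422 for number 1, 0.275 for number 2 and 0.285 for number 3, and all 6 correlations between different numbers were negative. The deviations of a group cancel out in each gene, so positive values for shared numbers force the other values to be negative on balance. The negative values are therefore not separate evidence of pairing. Any pairing is read from the same-number values, not from a statement in the labels. Genes are not independent replicates, so no p is attached to these correlations. The fit with the replicate block is an alternative: it called 7416 genes (1605 higher, 5811 lower) against 6017 without the block. Further alternatives changed the pseudocount, the filter, the scaling between libraries, the eBayes options, the summing over transcripts and the libraries used, and each library was left out in turn.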

Results

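Expression was measured in 6 RNA-seq libraries of MC3T3-E1 mouse osteoblast-like cells, 3 treated with vehicle and 3 with PTH(1-34), a hormone fragment that signals through a G protein-coupled receptor to cyclic AMP and protein kinase A. The labels give the treatment time as 30 min in one field and as 2 h in another. Libraries of a group resembled each other more than libraries of different groups: the lowest correlation of log2 values across genes within a group was 0.982 and the highest between groups was 0.953. The first principal component held 74.0% of the variance and separated vehicle from PTH, and the second, with 10.2%, ordered the libraries by their number in both groups. No pair of libraries held identical values in more than 0.138% of the tested genes.

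The series title concerns Nfil3, a basic leucine zipper transcription repressor, as a target of the coregulator NACA, and the first question was how both genes responded to PTH. Nfil3 rose 9.67-fold, from 14.5 ± 1.05 FPKM (SD, n = 3) in vehicle to 144.6 ± 7.33 FPKM (SD, n = 3) with PTH. On the log2 scale the rise was 3.27 (SE 0.07, limma adjusted p = 7.9e-07), with all 3 PTH libraries above all 3 vehicle libraries. The exact permutation test of the difference of means, two-sided, gave p = 0.1, the smallest that 3 against 3 libraries allow. Nfil3 (ENSMUSG00000056749) lies on the minus strand of chromosome 13 from 52967209 to 52981073 in mm10, and its single transcript in the table has 2 exons. Naca (ENSMUSG00000061315; chromosome 10, 128035575 to 128048637, plus strand), which encodes the alpha subunit of the nascent polypeptide-associated complex, stood at 427.1 ± 5.08 FPKM (SD, n = 3) in vehicle and 411.7 ± 18.9 FPKM (SD, n = 3) with PTH. Its log2 difference of -0.05 (SE 0.04) did not pass the threshold (limma adjusted p = 0.346) and changed sign to 0.07 when the libraries were centred on their medians.

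In the values as deposited, PTH was followed by a small number of very large rises and a large number of small falls, and the number of small falls depended on the scaling. Of 11628 genes tested, 6017 changed, 1252 of them higher and 4765 lower (limma, adjusted p under 0.05). Among the changed genes with a log2 change of at least 1 the balance was the other way, with 359 higher and 181 lower. The 3 PTH values lay wholly above the 3 vehicle values in 1528 genes and wholly below in 5520, together 60.6% of genes. Chance gives 10% only for libraries on the same scale. The median FPKM of the tested genes was 10.8 to 10.9 in the PTH libraries and 11.8 to 11.9 in the vehicle libraries. Part of the 60.6% may therefore come from the scaling, and the share was not computed with centred libraries. The median log2 change of all tested genes was -0.15, and centring each library on its median added 0.12 to every fold change. The centred values gave 2131 genes higher and 2792 lower, so the share of calls that were lower went from 79.2% to 56.7%. Cyclic loess, chosen after seeing the data, turned the balance to 2345 higher and 2051 lower, with a median of 0.01. Small changes therefore depend on the scaling, and list counts that move are given with deposited and with centred values.

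**Figure D1:**
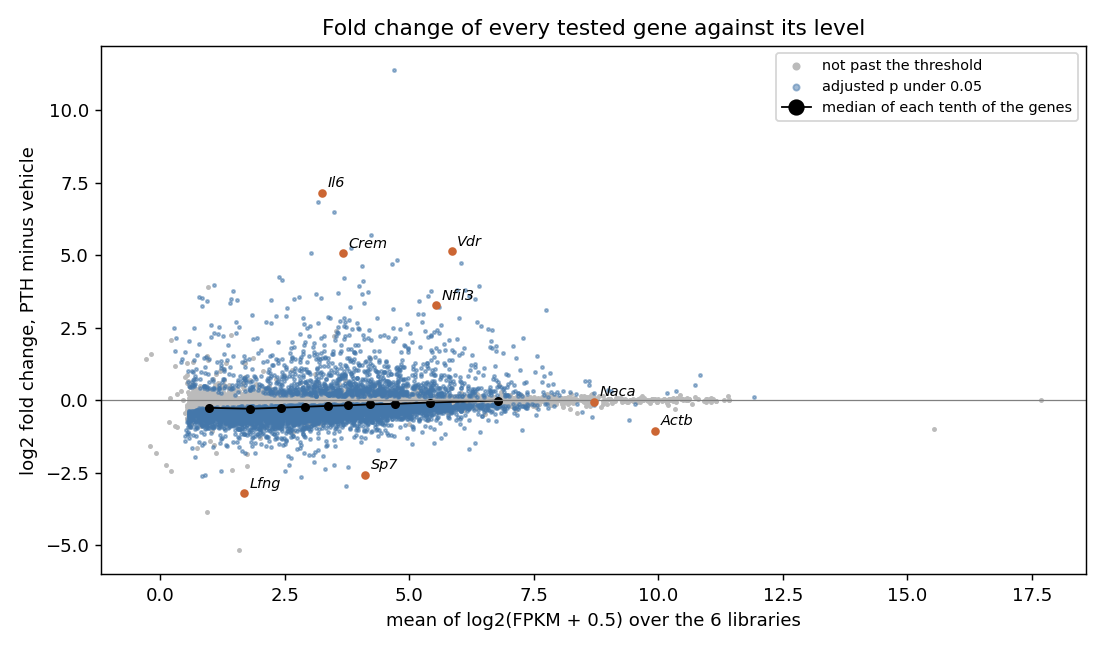
Log2 fold change (PTH minus vehicle) of each tested gene on the vertical axis against its mean log2(FPKM + 0.5) over the 6 libraries on the horizontal axis; blue points passed the threshold (limma adjusted p under 0.05), grey points did not, orange points are named. The black line joins the medians of 10 bins of genes by level, from -0.26 in the lowest bin to -0.01 in the highest.

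The 12 largest rises were in Il6, Kcne4, Nr4a3, Fos, Nr4a2, Vdr, Pde4b, Crem, Dusp1, Rgs2, Nr4a1 and Fosl1. Il6, which encodes a cytokine that osteoblasts release to drive osteoclast formation, went from 0.300 ± 0.0982 to 112.9 ± 8.78 FPKM (SD, n = 3 each), a log2 rise of 7.15 (SE 0.10, limma adjusted p = 1.7e-07). Vdr, the vitamin D receptor, went from 9.26 ± 0.797 to 342.4 ± 9.66 FPKM (SD, n = 3 each), a log2 rise of 5.14 (SE 0.06). The orphan nuclear receptor genes Nr4a3, Nr4a2 and Nr4a1 rose by 6.47, 5.25 and 4.69 on the log2 scale, and the AP-1 genes Fos and Fosl1 by 5.68 and 4.62. Pde4b, a cyclic AMP phosphodiesterase, rose by 5.08, Crem, a cyclic AMP-responsive transcription factor, by 5.07, Dusp1, a phosphatase of MAP kinases, by 4.83, and Rgs2, which shortens G protein signalling, by 4.73. Kcne4, a potassium channel subunit, rose by 6.83, from 0.340 ± 0.0377 to 95.2 ± 4.01 FPKM (SD, n = 3 each). The largest limma adjusted p among the 12 was 3.1e-05. With only the highest transcript of each symbol the rise of Nr4a2 was 4.26, and the size of the Il6 rise depended on the added constant (6.45 with 1, 8.17 with 0.1). Il6 lies on chromosome 5 from 30013114 to 30019981 (plus strand), Vdr on chromosome 15 from 97854425 to 97910630 (minus strand) and Crem on chromosome 18 from 3266048 to 3337748 (minus strand).

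The 12 largest falls were in Lfng, Rgs3, Dusp7, Sp7, Dusp27, Ctgf, Nuak1, Cdc42ep1, Fzd5, Lmcd1, Tnfaip3 and Ajuba. Lfng, a glycosyltransferase that modifies Notch receptors, went from 9.26 ± 1.44 to 0.553 ± 0.0329 FPKM (SD, n = 3 each), a log2 change of -3.20 (SE 0.11, limma adjusted p = 5.8e-06). Sp7 (osterix; chromosome 15, 102356606 to 102367182, minus strand), a transcription factor required for osteoblast differentiation, went from 42.7 ± 11.5 to 6.79 ± 1.60 FPKM (SD, n = 3 each), a log2 change of -2.56 (SE 0.24, limma adjusted p = 0.000283). Rgs3, a regulator of G protein signalling, changed by -2.97 and Dusp7, a phosphatase of the kinase ERK, by -2.65, so each family had a member among the largest rises and a member among the largest falls. Fzd5, a Wnt receptor, changed by -2.23 and Tnfaip3, which encodes the ubiquitin-editing enzyme A20, by -2.12. Nuak1, a kinase related to AMPK, changed by -2.37 and Cdc42ep1, an effector of the GTPase Cdc42, by -2.30. Dusp27 changed by -2.44 and the LIM domain gene Lmcd1 by -2.23. Ctgf had the least precise value of the 12 (-2.44, SE 0.40, limma adjusted p = 0.00265), with vehicle libraries between 7.15 and 24.0 FPKM.

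**Figure D2:**
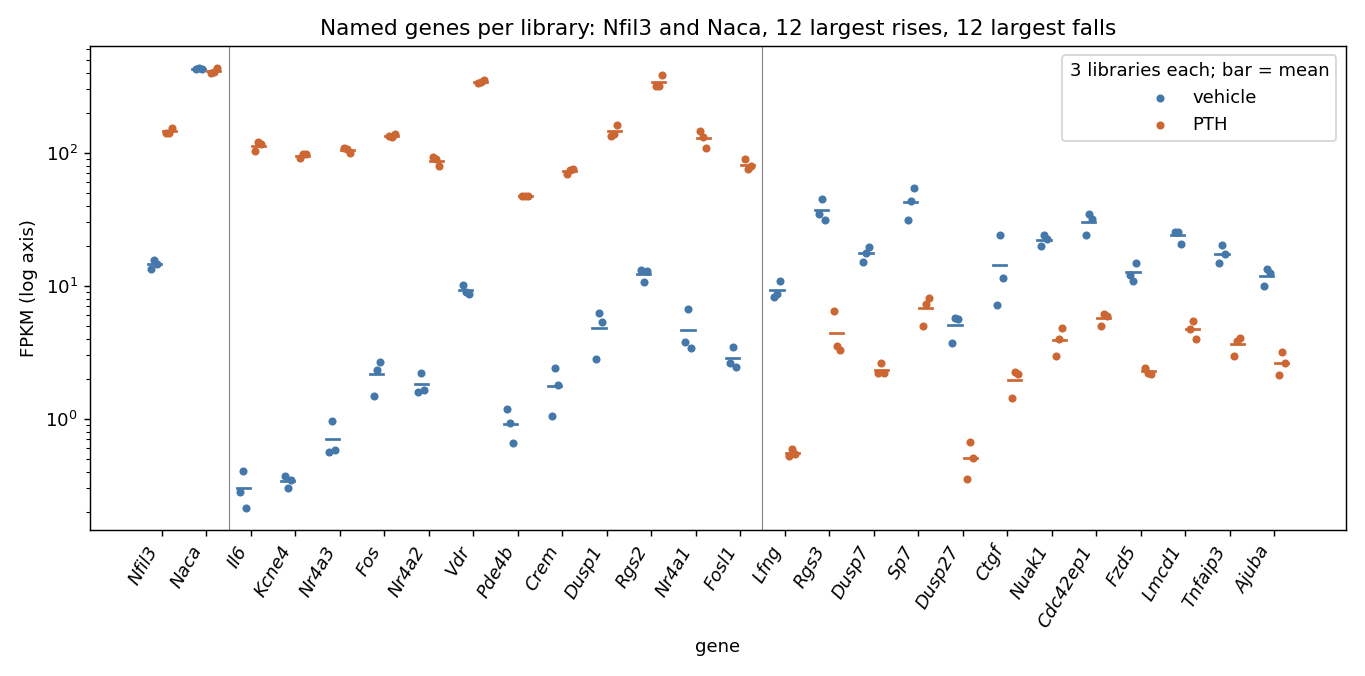
FPKM per library on a log axis for Nfil3 and Naca, the 12 genes with the largest rise and the 12 with the largest fall; points are the 3 vehicle (blue) and 3 PTH (orange) libraries and bars their means. Nfil3 sits between 13.4 and 15.5 FPKM in vehicle and between 139.5 and 153.0 FPKM with PTH, while the Naca libraries overlap.

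Genes of the cyclic AMP, protein kinase A and CREB pathway rose together. Of 20 tested, 17 rose and 2 fell, with the same counts when adjusted over the list alone; with centred libraries 17 rose and 1 fell. Besides the phosphodiesterase gene Pde4b and the Nr4a genes, the list holds Fos, Crem and Rgs2 among the largest rises. Pde4a and Akap12 were the members that fell, named after their values were seen. The list passed camera (adjusted p = 1.2e-18), and it also passed with adjusted p = 0.0210 with an estimated correlation. Of the 24 immediate-early transcription factors, 13 rose, led by Nr4a3, Fos, Nr4a2 and Nr4a1, and 3 fell; the counts were 14 and 3 adjusted over the list alone, 13 and 1 with centred libraries, and 16 and 4 with the replicate block. That list passed camera (adjusted p = 1.2e-11) and did not with adjusted p = 0.186 with an estimated correlation.

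Cytokines and paracrine factors known to respond to PTH, with some enzymes and receptors of their pathways, rose in 18 of 26 tested genes, both over all genes and adjusted over the list alone, and the other 8 did not pass. The replicate block gave 21 rises and 4 falls. After Il6, the largest rises were in Ptgs2 (cyclooxygenase 2; log2 4.20, SE 0.18), Vegfa (angiogenic growth factor; 3.60, SE 0.10, from 20.8 ± 1.43 to 257.6 ± 30.7 FPKM, SD, n = 3 each) and Areg (amphiregulin; 3.52, SE 0.12). The Areg value depended on the added constant (2.67 with 1, 5.52 with 0.1), and that of Vegfa was 4.30 with only its highest transcript. Areg was listed at 0.058, 0.016 and 0 FPKM in the vehicle libraries and at 5.60, 6.22 and 4.78 FPKM with PTH. The list passed camera (adjusted p = 4.0e-15), and it also passed with adjusted p = 0.0335 with an estimated correlation. Feedback regulators of MAP kinase signalling rose in 7 of 11 tested genes and fell in 2, likewise adjusted over the list alone. The largest rises after Dusp1 were in Dusp5 (2.93), Dusp14 (2.91; 1.87 with only its highest transcript) and Spry2 (2.83). This list passed camera (adjusted p = 7.4e-06) and did not with adjusted p = 0.122 with an estimated correlation.

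In the list of Nfil3 and related bZIP transcription factors, 7 of 13 tested genes rose and 3 fell. Adjusted over the list alone 8 rose and 3 fell, and 7 and 1 did with centred libraries. Nfil3 itself is counted among these rises, and again among those of the clock and study lists below. Cebpd rose by 3.41 (SE 0.10), close to Nfil3 itself, Cebpb by 3.14 (SE 0.10) and Maff by 2.01 (SE 0.14). Of 14 tested circadian clock genes 5 rose and 2 fell, also adjusted over the list alone; 5 rose and 1 fell with centred libraries, and 8 rose and 4 fell with the replicate block. The clock genes with the largest changes were Nfil3, Bhlhe40 (2.60, SE 0.25), Per1 (2.52, SE 0.10) and Rora (2.12, SE 0.09). Both lists passed camera (adjusted p = 3.3e-05 for bZIP and 0.000280 for the clock), and neither did with an estimated correlation (adjusted p = 0.188 for both). Of 8 genes that the study of Nfil3 and NACA concerns, 4 rose, also adjusted over the list alone, and 4 did not pass; these genes were chosen with knowledge of the study, so the list is not independent evidence of a direction. The 4 were Nfil3, Bglap, Bglap2 and Lrp6, a Wnt co-receptor (0.91, SE 0.09, from 19.3 ± 1.20 to 36.7 ± 3.80 FPKM, SD, n = 3 each). The replicate block gave 5 rises and 1 fall. This list passed camera (adjusted p = 0.000385) and did not with adjusted p = 0.188 with an estimated correlation.

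Osteoblast genes moved apart. Of 15 tested, 4 rose and 3 fell, also adjusted over the list alone; 4 rose and 2 fell with centred libraries, and 4 rose and 7 fell with the replicate block. Bglap, the osteocalcin gene, rose from 5.04 ± 2.17 to 26.9 ± 8.95 FPKM (SD, n = 3 each; log2 2.35, SE 0.36, limma adjusted p = 0.00204), and Bglap2 by 2.20 (SE 0.23). These are near-identical neighbouring copies on chromosome 3, so how their reads were divided is uncertain. Sp7 fell, as above, and Bmp4, a bone morphogenetic protein, fell from 75.8 ± 11.7 to 26.5 ± 1.26 FPKM (SD, n = 3 each; log2 -1.49, SE 0.11). The list's median log2 change was -0.26 while camera ranked it upwards against the other genes, and it did not pass (camera adjusted p = 0.187; 0.619 with an estimated correlation). In both groups the library numbered 1 held lower values of several of these genes; Ibsp, the bone sialoprotein gene, stood at 28.5 FPKM in vehicle 1 and 22.4 FPKM in PTH 1, against 58.6 to 99.0 FPKM in the other 4 libraries (chosen after its values were seen). Of 3 tested osteocyte markers, Pdpn (2.05, SE 0.09) and Irx5 (1.30, SE 0.08) rose, and 1 did not pass; 2 rose and 1 fell adjusted over the list alone and with the replicate block. The bone collagen genes Col1a1 and Col1a2, and Sparc, Postn and Sost, were not analysed here.

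Of the developmental signalling lists, TGF-beta and BMP targets held rises, while the Wnt and Notch lists held rises and falls. TGF-beta and BMP targets rose in 12 of 16 tested genes, and the other 4 did not pass; adjusted over the list alone, and also with centred libraries, 13 rose. Id3 and Id2, inhibitors of basic helix-loop-helix transcription factors, rose by 1.62 (SE 0.35) and 1.61 (SE 0.39). The list passed camera (adjusted p = 6.2e-10; adjusted p = 0.0210 with an estimated correlation). Of 20 tested Wnt genes 6 rose and 5 fell, also adjusted over the list alone, 6 rose and 3 fell with centred libraries, and 8 rose and 7 fell with the replicate block. Wnt4 (2.54, SE 0.28) and the receptor gene Fzd1 (1.55, SE 0.09) rose, while Axin2, a feedback inhibitor induced by Wnt signalling, fell by 1.32 (SE 0.25) and Wnt10b fell by 0.99 (SE 0.25). Without vehicle 3, the Wnt10b change was -0.86 and no longer passed (limma adjusted p = 0.0545), nor did it with cyclic loess (0.0562). The Wnt list passed camera (adjusted p = 0.0132) and lost the call with adjusted p = 0.186 with an estimated correlation. It also lost it with centred libraries (0.134; 0.121 with the replicate block added), with quantile normalisation (0.106), as TPM (0.266), with cyclic loess (0.236) and at a minimum of 5 FPKM (0.0717). Its median log2 change was -0.01 and its mean 0.07. All 6 tested Notch genes changed, 2 up and 4 down, also adjusted over the list alone, and 2 up and 2 down with centred libraries. Hes1, a target of Notch, rose by 1.79 (SE 0.24) and Notch1 by 1.00 (SE 0.09), while the ligand gene Jag1 fell by 1.31 (SE 0.14), besides Lfng. The Notch list did not pass camera (adjusted p = 0.978; 0.979 with an estimated correlation), and it passed fry, downwards (adjusted p = 0.000174).

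Targets of SRF and YAP, which include genes of the actin cytoskeleton, fell in 7 of 15 tested genes and rose in 2. The counts were 8 and 2 adjusted over the list alone, 5 and 2 with centred libraries, and 12 and 2 with the replicate block. Besides Ctgf and Ajuba, Ankrd1 fell by 1.23 (SE 0.19). The list did not pass camera (adjusted p = 0.562; adjusted p = 0.891 with an estimated correlation). It passed as TPM (0.0209), with cyclic loess (0.0360), with the replicate block and centring (0.00833) and without both number-1 libraries (0.0382). Cell cycle genes fell in 13 of 20 and rose in 2, also adjusted over the list alone, but only 4 fell with centred libraries while 2 rose. Aurka (-1.37, SE 0.21), Plk1 (-1.05, SE 0.24) and Ccne1 (-0.86, SE 0.13) fell, and Cdkn1b, an inhibitor of cyclin-dependent kinases, rose by 1.10 (SE 0.09). This list did not pass camera (adjusted p = 0.372; adjusted p = 0.708 with an estimated correlation), and it passed with fry (downwards, 0.0241), cyclic loess (0.0373) and the replicate block with centring (0.0212).

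Stress and unfolded protein response genes rose in 7 of 18 and fell in 4, also adjusted over the list alone, 10 rose and 3 fell with centred libraries, and 9 rose and 5 fell with the replicate block. Ddit4 (2.42, SE 0.10), Gadd45b (2.01, SE 0.14), the heat shock protein gene Hsph1 (1.75, SE 0.08) and Gadd45a (1.36, SE 0.14) rose. Cholesterol synthesis genes rose in 7 of 16 and fell in 2, also adjusted over the list alone, with 8 and 2 when centred and 9 and 4 with the replicate block. Cyp51 rose from 136.5 ± 5.64 to 302.3 ± 13.2 FPKM (SD, n = 3 each; log2 1.14, SE 0.05), Mvk by 0.88 (SE 0.21), Insig1 by 0.63 (SE 0.05) and Idi1 by 0.57 (SE 0.11). Both lists passed camera (adjusted p = 0.000196 and 0.000415), and neither did with an estimated correlation (adjusted p = 0.186 and 0.436). The cholesterol list did not pass fry (adjusted p = 0.0922), and it lost its camera call with quantile normalisation (adjusted p = 0.0629) and as TPM (0.0605). Of 14 interferon response genes only Ifit2 changed (-0.59, SE 0.15, limma adjusted p = 0.0153), with no call adjusted over the list alone, and 4 rises and 4 falls with the replicate block. The Ifit2 call was lost without the libraries numbered 1 (log2 -0.53, limma adjusted p = 0.102), with quantile normalisation (0.0624) and with cyclic loess (0.105). The interferon list did not pass camera (adjusted p = 0.128; adjusted p = 0.708 with an estimated correlation), and it passed without vehicle 2 (0.0231) or without PTH 3 (0.00579).

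Few markers of other cell types could be tested. Of 6 tested chondrocyte genes 2 rose, also adjusted over the list alone, with 3 rises when centred and 4 with the replicate block: Sox9 rose by 1.44 (SE 0.11) and Sox5 by 0.42 (SE 0.11), a call lost as TPM (limma adjusted p = 0.0588). That list passed camera (adjusted p = 0.0103) and lost the call with centred libraries (0.0580), with the highest transcript of each symbol (0.0624) and with adjusted p = 0.188 with an estimated correlation. One adipocyte marker, Cebpa, was tested and did not pass (-0.15, SE 0.11, limma adjusted p = 0.275). Of the haematopoietic markers, Lyz2 differed by -0.10 (SE 0.26, limma adjusted p = 0.772) and Cd14 stood at 2.22 ± 0.496 FPKM in vehicle and 3.32 ± 0.976 FPKM with PTH (SD, n = 3 each; limma adjusted p = 0.0960). Neither passed, also adjusted over the list alone, and Cd14 passed with the replicate block (0.47, limma adjusted p = 0.0046; 0.00212 with centring added), with quantile normalisation (0.0301), as TPM (0.0242), with cyclic loess (0.0250) and without PTH 3 (0.0386). Values were listed for only 2 of 10 adipocyte, 4 of 12 haematopoietic, 2 of 9 endothelial and 3 of 9 muscle markers. No listed endothelial or muscle marker reached the minimum. Markers without listed values, and mitochondrially encoded genes, were not analysed here, so their absence from the cells was not shown. Of 12 reference genes often used for normalisation, 2 rose and 3 fell; 2 rose and 2 fell adjusted over the list alone, and 3 and 2 did with centred libraries. Actb (beta-actin) fell from 1421 ± 168.3 to 684.7 ± 79.0 FPKM (SD, n = 3 each; log2 -1.05, SE 0.11, limma adjusted p = 0.000529). Ywhaz (0.28) and Gapdh (0.23) rose; both also passed with centred libraries but lost the call as TPM, Gapdh also with quantile normalisation and with the highest transcript of each symbol (0.11, limma adjusted p = 0.197). The reference list did not pass camera (adjusted p = 0.365; adjusted p = 0.532 with an estimated correlation). In all, 12 of 18 lists passed camera with the preset correlation and 3 with an estimated one, and 13 passed fry. Some lists share strong members, such as Nr4a1, Fos and Nfil3, so the passing lists are not separate pieces of evidence. Splits of the 6 libraries that mixed the treatments gave 5 to 15 lists with the preset correlation. The count of passing lists therefore does not set the treatment apart.

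**Figure D3:**
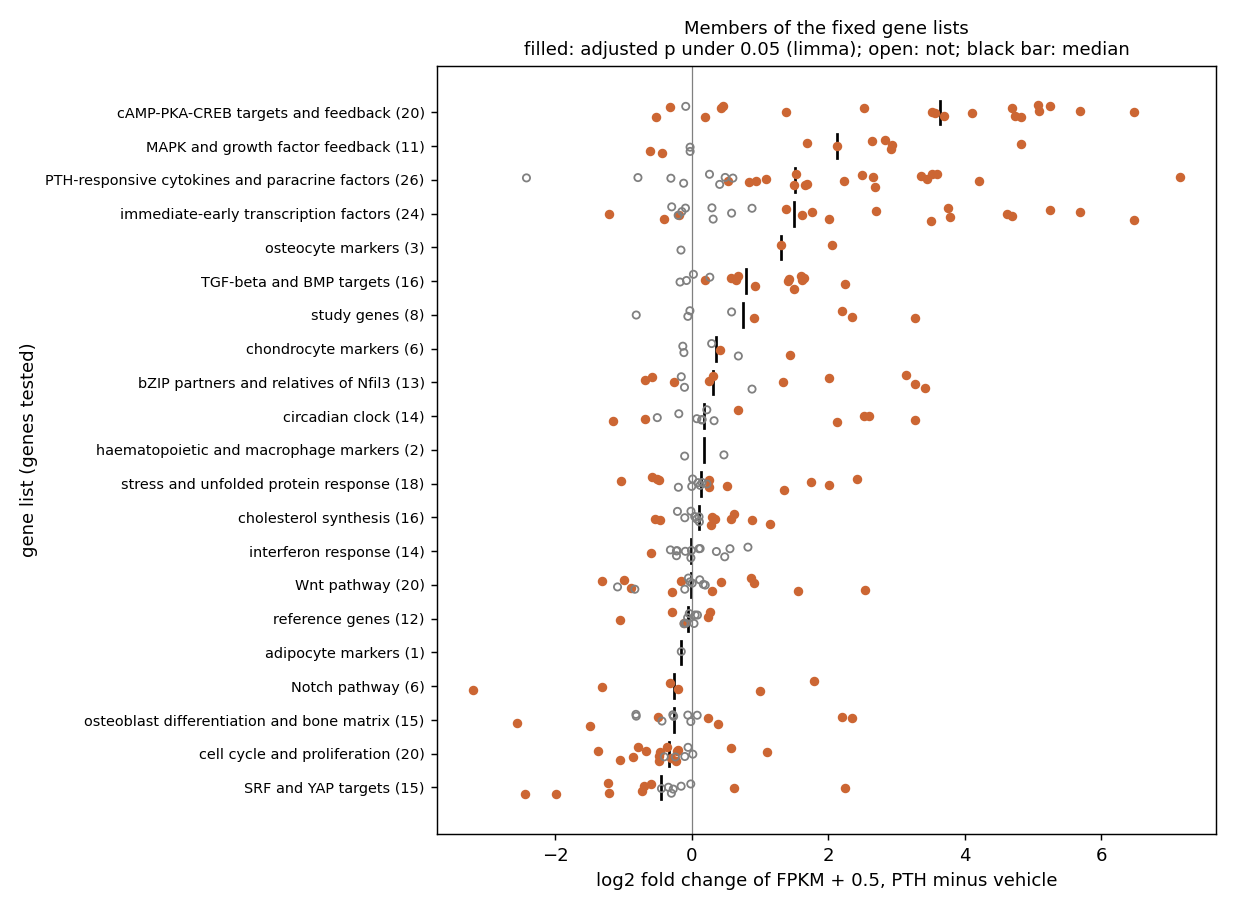
Log2 fold change (PTH minus vehicle, FPKM + 0.5) of each tested member of the fixed gene lists; 1 row per list with the number of genes tested, filled orange points past the threshold (limma adjusted p under 0.05), open points not, black bars the list medians. The median is 3.63 for the cyclic AMP list and -0.44 for the SRF and YAP list.

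At the level of single transcripts, 6670 of 21983 tested changed, 1787 higher and 4883 lower, and 2558 were higher and 2679 lower with centred libraries (limma). Of 4818 genes with at least 2 tested transcripts, 564 had transcripts that changed unequally on the log2(FPKM + 0.5) scale (limma diffSplice). That scale shrinks the change of low transcripts, so part of these calls may come from differences in level. The examples here were chosen after their values were seen. In Tsc22d1 the most abundant transcript, ENSMUST00000022587, went from 55.0 ± 3.59 to 584.3 ± 47.5 FPKM (SD, n = 3 each; log2 3.40), and the rarer ENSMUST00000134109 and ENSMUST00000133224 rose by 4.20 and 3.59, while ENSMUST00000048371 stood at 4.73 ± 0.541 and 4.32 ± 0.110 FPKM (SD, n = 3 each; limma adjusted p = 0.407). In Rcan1, a regulator of calcineurin, ENSMUST00000023672 rose by 1.40 (SE 0.09) and ENSMUST00000060005 fell by 1.30 (SE 0.15). In Nfatc1, a transcription factor controlled by calcineurin, ENSMUST00000035800 rose by 2.02 (SE 0.10) and ENSMUST00000167977 changed by -1.27 (SE 0.32, limma adjusted p = 0.0269).

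The transcripts of Crem were set apart by start site, as values only, since those with an upstream start lay under the minimum of the test. The gene is on the minus strand. GENCODE places the first base of 6 of its transcripts in the table between 3281078 and 3281769 of chromosome 18, called internal here. That of 4 others lies upstream of these, between 3299556 and 3337574. Upstream is relative to the internal group, since the upstream starts also lie within the coordinates of the gene. The 6 internally started transcripts summed to 0.153, 1.37 and 0.680 FPKM in the vehicle libraries and to 44.4, 46.3 and 45.9 FPKM with PTH. The 4 upstream ones summed to 0.619, 0.892 and 1.09 FPKM in vehicle and to 1.32, 1.12 and 1.43 FPKM with PTH. Both sums were thus higher in all 3 PTH libraries. The upstream rise rested on ENSMUST00000151311 (listed at 0 FPKM in the vehicle libraries, log2 1.12). ENSMUST00000154135 changed by -0.56, and ENSMUST00000130047 and ENSMUST00000142690 by 0.07 each. The 2 remaining Crem transcripts of the table, whose start is not in that annotation, summed to between 0.042 and 0.287 FPKM in vehicle and between 23.0 and 27.8 FPKM with PTH. The internal promoter of Crem is known as the origin of ICER, a family of short repressor proteins induced by cyclic AMP.

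**Figure D4:**
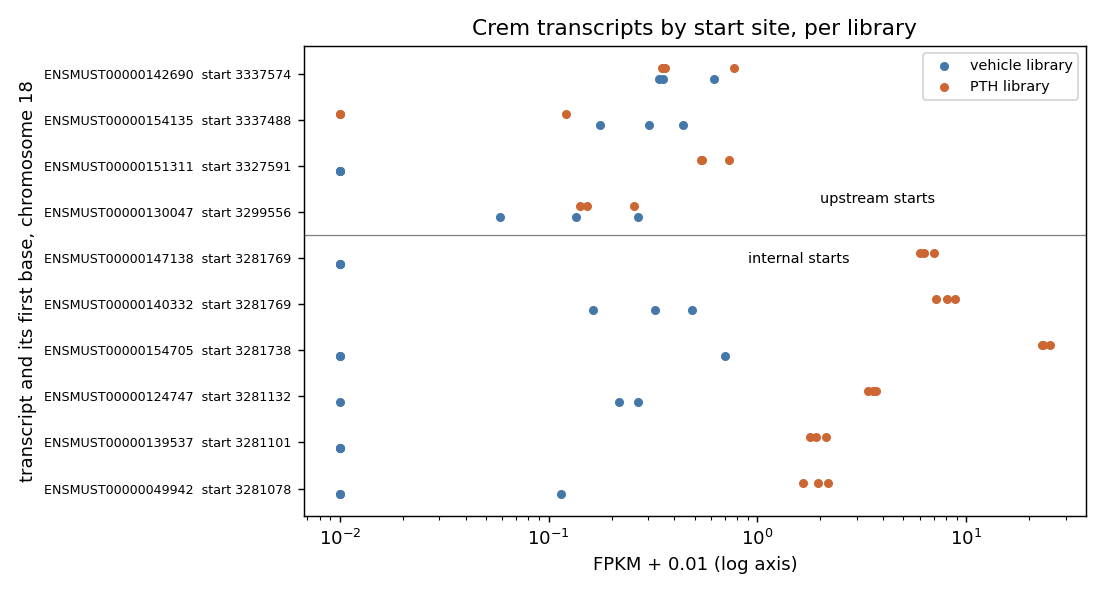
FPKM of 10 Crem transcripts per library (FPKM + 0.01, log axis), ordered by the position of their first base on chromosome 18, with the 6 internal starts below the line and the 4 upstream starts above it; blue points are the 3 vehicle libraries and orange points the 3 PTH libraries, and points at 0.01 are listed at 0. The internally started transcripts reach at most 25.1 FPKM with PTH and the upstream ones stay below 0.764 FPKM in every library.

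The authors' deposited table gives its own test per transcript, with 2855 transcripts at a q of 0.05 or less, 1462 of them up and 1393 down in group q2. Across 21935 transcripts its fold changes correlated with those computed here (Pearson 0.909; transcripts are not independent replicates) with q2 as PTH, which sets that direction. Of the 2475 of these transcripts that were tested here, 99.9% had the same sign and 2152 also passed (limma). Conversely, 32.3% of the 6670 transcripts called here had such a q in the authors' deposited table. For the transcript of Nfil3 the authors' deposited table gives a log2 fold change of 3.48, for Sp7 -2.49 and for Lfng -3.91, each with a q-value of 0.00111, and for Naca 0.11 with a q-value of 0.947. Some large rises here did not reach 0.05 in the authors' test. There the transcript of Areg had a q-value of 0.335. Of the tested Crem transcripts, ENSMUST00000140332 had 0.0461, while ENSMUST00000124747 had 0.211, ENSMUST00000147138 0.583, ENSMUST00000154705 0.566, ENSMUST00000182204 0.110 and ENSMUST00000182833 0.601. The median log2 fold change of the transcripts tested in both was 0.02 in the authors' deposited table and -0.13 here.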

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

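Genes of the fixed lists that stayed under the mean of 1 FPKM were outside the test, and 24 such genes were looked at after the other results were known. In 5 of them all 3 PTH libraries lay above all 3 vehicle libraries, in 3 they lay below, and the fit without a filter gave an adjusted p under 0.05 (limma), which is the reason they are listed. Tnfsf11, which encodes RANKL, the cytokine that osteoblast-lineage cells present to osteoclast precursors, was listed at 0.0386, 0 and 0 FPKM in vehicle and averaged 0.298 ± 0.0554 FPKM with PTH (SD, n = 3; log2 0.64, limma adjusted p = 0.00182 without a filter). The level is far below that of Il6, and the depth behind it is unknown. Nog, a secreted BMP antagonist, averaged 0.160 FPKM in vehicle and 1.05 FPKM with PTH. Dusp4 and Spry4, feedback regulators of MAP kinase signalling, averaged 1.33 and 0.545 FPKM with PTH against 0.358 and 0.243 FPKM in vehicle, and Cnn1, a smooth muscle calponin, averaged 0.741 FPKM with PTH against 0.335 FPKM in vehicle. The 3 lower genes were Dll1, a Notch ligand (0.376 FPKM in vehicle, 0.164 FPKM with PTH; log2 -0.40, limma adjusted p = 0.00832 without a filter), Comp, a cartilage matrix protein (0.530 and 0.307 FPKM; -0.35, 0.0168), and Eng, an endothelial co-receptor of TGF-beta (0.264 and 0.0719 FPKM; -0.42, 0.0175). Groups of 3 libraries are too small for a check of single outlying libraries, and the series has 1 contrast, so no difference between contrasts was looked for.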

How the results depend on the processing

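Each library left out in turn gave 5007 to 5633 changed genes, 1071 to 1178 higher and 3936 to 4455 lower, 4576 to 5467 transcripts and 12 to 13 lists. Nfil3 stayed past the threshold in all settings, with log2 changes from 3.22 to 3.40. Scaling moved the split: median centring gave 2131 genes higher and 2792 lower, and quantile normalisation 3096 lower. TPM gave 2018 changed genes, 1158 of them lower; Mir5105 takes 19.0% to 39.6% of the FPKM totals and so enters every TPM value. A log2 change of at least 1 left 540 genes (359 higher, 181 lower), by construction. An estimated correlation left 3 lists. Several settings were chosen after seeing the data. Among these, cyclic loess, which removes a trend with level, gave 2345 higher and 2051 lower, the replicate block with centring 2890 higher and 3593 lower, and leaving out both number-1 libraries 5363 changed genes. The paired fit with the replicate block alone gave 7416 genes, 7590 transcripts and 12 lists and, of the named genes and lists, changed only the call of Cd14. Signs turned only in genes that did not pass: Naca became 0.0702 with centring (with or without the block) and 0.0393 as TPM; Lyz2 0.0234 with centring (with or without the block), 0.0450 with quantile normalisation, 0.11 with cyclic loess and -0.32 to 0.11 with 1 library left out; and Cebpa 0.0526 with quantile normalisation and 0.11 with cyclic loess. The cause of these turns was not tested. Pseudocounts, eBayes options and the absence of a filter changed no call of a named gene or list. A minimum of 5 FPKM left 10 lists: the Wnt list lost its call, and the chondrocyte list kept too few genes to be tested. The highest transcript of each symbol gave 5257 genes and 11 lists. Quantile normalisation and TPM each lost the cholesterol and Wnt lists, and TPM the call of Sox5. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many as 6017 genes and the highest other gave 2; 1 gave as many as 6670 transcripts and the highest other gave 2; and 3 gave as many as 12 lists, the highest other 15. With 10 splits no share can fall under 0.05. The other 3 splits that part all pairs gave at most 2 genes and 11 lists. Each split but the real one sets 2 libraries of a treatment against 1, so part of the treatment difference remains in it. Unknown depth keeps the precision of low genes unknown.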

Other observations

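All tests in this part were chosen after the result they bear on was seen. The libraries numbered 1 differed from the other 4. In a fit with treatment and number 1 as terms, 323 of 11628 genes differed (limma adjusted p under 0.05), 191 higher and 132 lower. The same fit for number 2 gave 0 genes (1255 at an unadjusted p under 0.05) and for number 3 gave 10. The fit assumes an equal deviation in both groups, so it does not test that. It also treats both libraries of a number as independent. On the second principal component number 3 lay at the end opposite to number 1. Smpd3 and Phospho1, enzymes of matrix mineralisation, differed by -1.77 and -1.69 on the log2 scale, Ibsp by -1.68 and Ifitm5, an osteoblast membrane protein, by -1.54, and by less Pth1r, the PTH receptor gene (-0.92), and Alpl, the alkaline phosphatase of bone (-0.65). These genes were picked from the result, and Smpd3 and Ifitm5 are not in the fixed osteoblast list. Pth1r stood at 26.9 FPKM in vehicle 1 against 51.9 and 51.2 FPKM in the other vehicle libraries, and at 15.2 FPKM in PTH 1 against 26.8 and 31.6 FPKM in the other PTH libraries. Higher in number 1 were Gpnmb (1.42), the collagenase gene Mmp13 (1.33), Nov (1.15), Sfrp2 (1.04) and Lum (0.83), and, among the 4 of 20 fixed cell cycle genes that were higher, Plk1 (0.64), Aurka (0.57) and Ccnb1 (0.48). The clock gene Per2 differed by -1.12.

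Of the 15 tested genes of the fixed osteoblast list, 7 were lower and 0 higher in the number-1 libraries, with a median of -0.60 over the list. For number 3 the same list leaned the other way (median 0.34, camera adjusted p = 0.00151 with the preset correlation), with no member past the threshold (limma) and with the number-1 libraries among the other 4. An estimated correlation was not computed for number 3. A trend with GC content and transcript length, fitted over all genes with such values, held 3.10% of the variance of the number-1 deviation and came to at most 31.3% of the deviation of any of the 318 such genes that differed. After its removal 100% of them kept at least 50% of their deviation (exact 95% binomial interval from 98.8%, which treats genes as independent). The bound of 31.3% already fixes that outcome, so it adds no evidence. By its size alone, this fitted trend was not the whole cause. A hypothesis is that the number-1 cultures may have been less far along osteoblast differentiation. Genes outside that list, such as those of the clock, also differed, and no other state of the cultures was tested. The list passed camera with the preset correlation (adjusted p = 8.7e-05), but its p with an estimated correlation was 0.0791 (adjusted p = 0.296). The bound as first written for this test counted a p of 0.05 or more against the hypothesis, and the value met it. That bound was wrong: a p that misses the threshold does not show absence, and 7 members were lower against 0 higher, so the hypothesis stays open, without support from this p. A shared day of culture, library or sequencing for the number-1 pair was not tested, since the labels give none, and no group of the design stands for a biological alternative.

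The excess of falls was larger in genes of low level than in those of high level. Over 10 bins of genes by level the median log2 change was -0.26 in the lowest, -0.29 in the second and -0.01 in the highest, and 460 genes fell against 88 that rose in the lowest bin, 581 against 65 in the second and 162 against 146 in the highest, so the excess peaked in the second bin. In these libraries the highest and lowest bins differed by 0.25 (95% bootstrap interval 0.22 to 0.28). A single scaling factor per library therefore cannot be the whole cause in them, though it may account for a constant part. The bootstrap intervals in this paragraph resample genes within bins, so they do not measure the spread between libraries. GC content and transcript length do not account for the trend, as the difference was 0.26 before and 0.25 after removing them (0.22 to 0.28) in the 11468 genes with such values. An equal background added to every gene in the vehicle libraries would give equal losses in FPKM, and the median loss of the 8th bin was 5.83 times that of the lowest (4.99 to 7.30), at 2.16 against 0.370 FPKM, with 0.781 FPKM in the highest bin. A wide decline of less abundant mRNA with PTH, and a step of the authors' normalisation that depends on level, stay open; the authors' deposited fold changes, with a median of 0.02 over the tested transcripts, are on another scale.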
